A study of Mus musculus with 14 samples.

How the data were processed

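The series measured mouse intestinal organoids, cultures of intestinal epithelium that grow from its stem cells, in ENR medium (EGF, Noggin and R-spondin1). Single-cell RNA-seq (10x Genomics) covered 4 libraries: untreated wild-type organoids, untreated organoids with a Chgb-mCherry knock-in reporter, and reporter organoids after 6 days of 0.05% DMSO or of 25 µM Isx-9, a small molecule. Bulk RNA-seq covered stem cells sorted from Lgr5-EGFP knock-in organoids after 6 hours of DMSO or Isx-9, with 2 libraries each (RNeasy RNA, NEBNext Ultra RNA kit, which does not mark the strand). The 6 ATAC-seq samples of such stem cells, 3 per treatment, were not analysed here.

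The bulk files hold whole-number counts per gene that the authors deposited. Per the submitters' processing notes, which name tools without their order, these come from Trim Galore 0.6.4, HISAT2 (version not given in the sources used here) and HTSeq 0.12.4 on GRCm38. The annotation release, the strand setting and the aligner's options were not given in the sources used here. The values of the single-cell matrices are UMI counts per gene and cell, deposited without normalization, from Cell Ranger 3.1.0 and Seurat 3.1.5 per the submitters' processing notes. In the 4 matrices every barcode had at least 500 UMIs and 200 genes. The authors also deposited a table of bulk differential expression from DESeq2 1.24.0. Its signal column is the mean of the size-factor-normalized counts, computed by the authors. Its log2 fold changes and their standard errors, its score (the Wald statistic) and its p-values, raw and adjusted, are likewise the values that the authors deposited. No genome annotation was used here, so genes carry their symbol and identifier without chromosomal positions.

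Bulk counts were analysed in R 4.3.3. Genes were filtered with filterByExpr, scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test, 2 against 2 libraries, 2-sided), and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Bulk CPM are TMM-scaled. The labels do not say that the replicates came from separate cultures, so these p-values measure only the spread between these libraries. Rose and fell are used of bulk genes and lists that passed this test. For genes with 0 counts in both DMSO libraries, the fold is a lower bound against a floor of 3 counts over the group. For genes with 1 to 3 counts there, the ratio of counts is given with its exact 95% interval. Intervals and floors, here and in single cells, cover counting error only. The test was run on simulated data in which 200 of 17418 genes were changed, and it recovered 37.5% of them at a fold of 1.5, 69.5% at 2 and 88.5% at 4, with 0, 7 and 11 false calls. These were few genes, changed up as often as down, so the simulation did not cover errors of scaling where many genes change.

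Before the data were examined, the comparisons, tests, 29 gene lists, the rule for named genes and the alternatives below, except where stated, were fixed. The lists hold markers of stem cells, proliferation, enterocytes, goblet, Paneth, tuft and enteroendocrine cells (a pan-enteroendocrine list, transcription factors, hormones and amines, and an enterochromaffin list), members or targets of the Notch, Notch ligand and secretory progenitor, Wnt, immediate early, calcium, BMP, EGFR-MAPK, YAP and fetal-like, cholesterol synthesis, AhR, NRF2, unfolded protein, heat shock, p53 and interferon responses, and neuronal, mesenchymal, immune, and endothelial and glial genes. Some genes stand in more than 1 list. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1, voom values, preset correlation of 0.01), with p-values adjusted over the lists. The rule for bulk named the 10 highest and 10 lowest log2 fold changes among genes with an adjusted p under 0.05, at least 5 CPM in the higher group and both libraries of 1 group above both of the other, without predicted Gm and Rik genes. It added 12 genes whatever their result (Neurog3, Neurod1, Insm1, Atoh1, Chga, Chgb, Lgr5, Ascl2, Olfm4, Mki67, Fos and Nr4a1) and up to 4 members of each list that passed the test, with the largest absolute log2 fold changes. Of the 10 highest, 1 is not reported here, and not every list member so named is printed. For single cells it named 21 genes whatever their result, the 10 genes with the highest and the 10 with the lowest ratio in all cells and in enteroendocrine-like cells (at least 100 UMIs over both libraries, at least 10 in the lower), and up to 4 members of each list.

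Cells with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept, and doublets were called per library with Scrublet in scanpy 1.11.5. The 4 libraries were normalised to 10000 UMIs per cell, log-transformed and clustered together without batch correction (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1; Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9). Each cluster's nearest list was the class with the highest mean log2 fold over its markers, where markers that were lower counted as unchanged. A nearest list therefore does not mean that most of its markers were higher. The cluster took that name where at least 3 markers stood among its leading 10 genes. It also took the name where at least 3 markers, each in at least 10% of its cells, were at least 2-fold higher than in the other cells, and either 1 stood among the leading genes or as many of the list's genes were higher as were not. This naming rule was revised once after the clusters were seen; the enteroendocrine-like (EEC-like) clusters were the same under both versions. A cluster lost its name where another class had more markers among the leading genes. It also did so where its cells had few UMIs for their library and no own marker stood among the leading genes. Clusters that met no rule or lost their name were left unnamed, and their share is given for each library.

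With 1 library per condition, single-cell results carry no test. Class shares have exact 95% binomial intervals. Gene levels are UMI sums over all cells, or over the cells of a class with at least 50 cells in both libraries, as CPM, and their ratios have exact Poisson intervals. The median log2 ratio of each list (1 CPM added, members with at least 20 UMIs) was placed among 10000 random lists of the same size matched on mean expression. For hormone-positive shares each cell with at least 2000 UMIs was thinned to 2000, and cells with fewer were left out. Bulk calls were looked up in the single-cell sums at 6 days.

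The alternatives were DESeq2 1.42.0, RLE factors, no low-count filter or a CPM filter, the replicate number as a block, a fold minimum, limma-voom, each bulk library left out, camera with an estimated correlation, fry, other cell filters, doublets kept, Leiden resolutions of 0.5 and 2, each library clustered alone, enteroendocrine lists left out of the variable genes, a definition of EEC-like cells by UMIs alone, cell-weighted means, TMM-scaled sums, unthinned cells, a minimum of 3 UMIs, a threshold of 0.01 and sums over all cells. Setting the median log2 of each bulk list against 10000 random lists drawn from the 200 tested genes nearest in level to each member (DMSO mean CPM, or the mean over the 4 libraries; 2-sided, Benjamini-Hochberg over lists with at least 5 tested members), scaling bulk counts by library size alone, clustering without any cell type marker list and comparing the reporter only with Y-linked wild-type cells were added after seeing the data. The rule that leaves the Epcam share undecided where nearly all UMIs lie in cells with Epcam was added after its value was seen, and changed that label from against the explanation to undecided. The share of 4 differentiated classes together, the count of hormone peptides that were lower and the list medians used to compare single-cell settings were also chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.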

Results

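The data comprised 4 single-cell RNA-seq libraries of mouse intestinal organoids and 4 bulk RNA-seq libraries of sorted intestinal stem cells. The single-cell libraries were untreated wild type, untreated Chgb-mCherry reporter, and reporter after 6 days of DMSO or of 25 µM Isx-9, with 1 library each. They held 139401464, 134346948, 132150411 and 116046871 UMIs in 10830, 11885, 11632 and 12201 deposited cells. After filtering, 8744, 9609, 8964 and 9156 cells were analysed, with medians of 15007, 12631, 13379.5 and 8881 UMIs per cell. The bulk libraries held 19487264 and 18909542 counts for DMSO and 19025875 and 19431905 for Isx-9, 6 hours after treatment began. There was no replicate of any single-cell condition, so single-cell values carry counting intervals and no test. According to its title, the series addressed whether Isx-9 drives organoid cells towards enteroendocrine cells, the hormone-secreting cells of the gut epithelium.

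The bulk libraries of stem cells treated with Isx-9 for 6 hours held reads of genes that had none in DMSO; whether all of these were transcripts of the stem cells was not settled. Lrp2 (ENSMUSG00000027070), an endocytic receptor, had 0 counts in both DMSO libraries and 32.0 ± 12.7 CPM (SD, n = 2) with Isx-9, at least 391-fold higher. Bend4 reached 30.3 ± 2.90 CPM (at least 371-fold higher), Hdgfl3 22.7 ± 10.2 CPM (at least 278-fold higher) and Basp1, a growth-cone protein of neurons, 12.8 ± 4.82 CPM (at least 157-fold higher), each from 0 in DMSO. Arhgef25, the homeobox gene Esx1, Cpeb1, Sfmbt2 and Slc38a3 were also among the 10 highest, each from 0 in DMSO, with lower bounds from 179-fold for Slc38a3 to 199-fold for Arhgef25. Neurog3 (ENSMUSG00000044312), the transcription factor that commits gut cells to the enteroendocrine fate, rose from 8.38 ± 2.87 to 20.8 ± 2.73 CPM (log2 fold change 1.31, SE 0.23, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0008).

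The lowest fold changes were smaller in size. Rab43, a small GTPase, fell by 2.89 on the log2 scale (SE 0.42), followed by Pnpla1 (-1.99), Fbxl20 (-1.74), Washc2 (-1.71), Hdc, which encodes the enzyme that makes histamine (-1.66), Entpd8 (-1.63), Nagpa (-1.58) and Uqcc3 (-1.51). Isx, an intestinal homeobox gene that shares only its name with the compound, fell from 111 ± 0.0959 to 37.1 ± 0.318 CPM (SD, n = 2 each; log2 fold change -1.58, SE 0.09). Among the 10 lowest, mt-Co3 rested on 1 library: it had 30.5 and 118 CPM in the DMSO libraries, and its log2 fold change of -1.54 became -0.27 without DMSO replicate 2 (adjusted p = 0.19, edgeR quasi-likelihood, Benjamini-Hochberg), with a call that was also lost under 4 other alternatives. As a mitochondrial gene with copies elsewhere in the genome, its level is uncertain. Each bulk gene described here as having risen or fallen had both libraries of 1 group above both of the other.

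Of 17418 genes tested, 8243 passed the threshold, 4755 higher and 3488 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), with a median log2 fold change of 0.02 over all tested genes. Changes of at least 2-fold made up 3356 of the rises and 154 of the falls. There were 4270 genes with 0 counts in both DMSO libraries, of which 362 reached a mean of at least 1 CPM with Isx-9, while 0 of the 1467 genes at 0 in both Isx-9 libraries reached 1 CPM in DMSO. Direction went with level. Of 2520 genes over 100 CPM in DMSO 58.4% fell and 4.13% rose (median log2 -0.26), of 2380 at 0.1 to 1 CPM 49.7% rose, and of 901 under 0.1 CPM all rose, which the low-count filter fixes, since it keeps such genes only for their Isx-9 counts. The filter acts in part at 0.1 to 1 CPM too, where 0.504% fell. The lists were therefore also set against random lists of the same DMSO level, a test chosen after seeing the data that treats genes as independent. The Isx-9 libraries had a count for 23881 and 23695 genes and the DMSO libraries for 21237 and 20942, at similar totals. Scaling by library size alone, chosen after seeing the data, moved the median log2 of all genes to 0.14 and left 5475 higher and 2095 lower genes, with 6850 of the 8243 calls kept and 0 turned. Without Isx-9 replicate 1 the number of lower genes was 2062, and 1 call turned direction.

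Stem cell and cell cycle genes fell about as far as other genes of their level. Of 18 stem cell markers 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median log2 of -0.33 and a camera adjusted p of 1.1e-04, or an adjusted p of 0.842 with an estimated correlation. Random lists of the same DMSO level had a median of -0.26, with 56.9% of their genes falling, and the list lay at their 12.2nd percentile (adjusted p = 0.455). Olfm4, a secreted marker of crypt base stem cells, fell from 5981 to 4214 CPM (log2 fold change -0.51, SE 0.11, adjusted p = 0.00304, edgeR quasi-likelihood, Benjamini-Hochberg, n = 2 each). Cdca7 (-0.81), Rgmb (-0.65) and Slc12a2 (-0.58) fell, and Tnfrsf19, a Wnt target, rose (0.67), a call lost without DMSO replicate 2 or Isx-9 replicate 1 and with no low-count filter. Lgr5, the receptor by whose reporter the cells were sorted, had a log2 fold change of -0.18 (SE 0.08, adjusted p = 0.0715, edgeR quasi-likelihood, Benjamini-Hochberg) and did not pass, except without DMSO replicate 2 (-0.26, adjusted p = 0.0274). Ascl2, a stem cell transcription factor, passed at -0.29 (SE 0.10, adjusted p = 0.0374) and lost its call under 7 alternatives. Of 28 proliferation genes 18 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.27 and a camera adjusted p of 1.1e-05; with an estimated correlation the adjusted p was 0.842. Random lists of the same level had a median of -0.26 and 56.4% of genes falling, and the list lay at the 41.3rd percentile (adjusted p = 0.890). With library size alone 10 fell and the median was -0.15. The replicative helicase genes Mcm5 (-0.68), Mcm7 (-0.65) and Mcm4 (-0.58) and the thymidine kinase Tk1 (-0.57) changed most, while Mki67 stayed at -0.01 (SE 0.07, adjusted p = 0.903).

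Neuronal genes rose at 6 hours. Of 21 members 13 were tested and all 13 rose (13 adjusted over the list alone), with a median log2 of 4.62 and a camera adjusted p of 1.2e-05, or an adjusted p of 0.842 with an estimated correlation. For members near 0 in DMSO the filter fixes the direction. Among random lists of the same DMSO level, which had a median of 2.19 and 58.8% of genes rising, the list lay at the 99.6th percentile (adjusted p = 0.0364). Map2, a microtubule protein of dendrites, had 1 count over both DMSO libraries, and its ratio was 823 (147 to 32544). Ncam1, a cell adhesion protein, was at least 40.9-fold higher. Syn1, a protein of synaptic vesicles, had 3 counts in DMSO and a ratio of 45.2 (15.2 to 222). Elavl3, an RNA-binding protein, rose from 0.409 ± 0.0452 to 17.1 ± 1.32 CPM (log2 fold change 5.36, SE 0.31).

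Enteroendocrine lists held genes that rose, though in smaller shares than genes of their DMSO level, and none of the 4 passed the camera test. In the order below, 29.2, 26.7, 11.1 and 18.2% of members rose, against 32.1, 28.1, 38.0 and 23.5% of tested genes of the same DMSO level. None passed against random lists of that level (lowest adjusted p = 0.143). Of 24 pan-enteroendocrine genes 7 rose and 2 fell (7 and 1 adjusted over the list alone; median 0.70, camera adjusted p = 0.436). Pcsk1n (3.58), an inhibitor of prohormone convertase, the exocytosis genes Snap25 (2.86) and Syp (2.18), and the convertase gene Pcsk1 (1.42) rose, and the call of Pcsk1n was lost without Isx-9 replicate 1 and with no low-count filter. Of 30 enteroendocrine transcription factors 8 rose and 3 fell (8 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 0.436). Lmx1b had 1 count in DMSO and a ratio of 490 (87.5 to 19381), and Zcchc12 (3.69), Lmx1a (2.83) and Etv1 (1.97) rose, the last without a call when Isx-9 replicate 1 was left out. Neurod1 (-0.41, SE 0.46, adjusted p = 0.503), Insm1 (0.48, SE 0.23, adjusted p = 0.113) and Atoh1, the regulator of secretory fate (-0.06, SE 0.28, adjusted p = 0.884), did not pass (edgeR quasi-likelihood, Benjamini-Hochberg). Of 9 hormone genes tested, Penk, the enkephalin precursor, rose (at least 27.5-fold higher) and 0 fell, over all genes and adjusted over the list alone, and the median of -0.28 and the camera direction (lower, adjusted p = 0.863) opposed the mean of 0.77. Of 11 enterochromaffin genes Lmx1a and Gch1 (1.07) rose and Chga fell (2 and 0 adjusted over the list alone), with a median of -0.11 and a camera adjusted p of 0.954, lower, against a mean of 0.26, and the median was 0.02 with library size alone. Chga, a granule protein, passed at -0.71 (SE 0.25, adjusted p = 0.0357) and lost that call under 7 alternatives, with -0.31 (adjusted p = 0.323) without DMSO replicate 2. Chgb stood at -0.39 (SE 0.17, adjusted p = 0.0847), below the threshold without DMSO replicate 1 (adjusted p = 0.00287), without Isx-9 replicate 2 (adjusted p = 0.0414) and with a replicate block (adjusted p = 0.00523; edgeR quasi-likelihood, Benjamini-Hochberg).

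BMP pathway and immediate early genes rose. Of 17 BMP genes 12 rose and 2 fell (12 and 2 adjusted over the list alone), with a median log2 of 0.79 and a camera adjusted p of 0.00911, or an adjusted p of 0.842 with an estimated correlation. The ligand gene Bmp4 was at least 36.9-fold higher, and Smad9 (3.28), Id4 (2.57) and Id3 (1.92), which encode a signal transducer and inhibitors of differentiation, rose. Of 35 immediate early genes 18 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 0.35 and a camera adjusted p of 0.00325, or an adjusted p of 0.977 with an estimated correlation. The transcription factors Egr4 (3.60) and Egr3 (12.8 ± 4.25 to 122 ± 9.77 CPM, log2 fold change 3.25, SE 0.17), the phosphatase gene Dusp2 (2.45) and Arc (2.28) rose most. Nr4a1, an orphan nuclear receptor, rose by 0.85 (SE 0.11, adjusted p = 0.000121, edgeR quasi-likelihood, Benjamini-Hochberg) and Fos by 0.26 (SE 0.09, adjusted p = 0.0292), the latter lost under 3 alternatives. Of 16 NRF2 targets 9 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.28, camera adjusted p = 0.00969), and this call was lost without Isx-9 replicate 1 and with an estimated correlation (adjusted p = 0.977). Among random lists of the same DMSO level, with a median of -0.22 and 44.5% of genes falling, the list lay at the 17.6th percentile (adjusted p = 0.579). The pentose phosphate genes Pgd (-0.74) and G6pdx (-0.59) and the glutathione reductase gene Gsr (-0.64) fell, and Srxn1 (0.58) rose. With an estimated correlation 0 of the 6 camera list calls held. Against random lists of the same DMSO level the 3 higher ones did (BMP adjusted p = 0.0101, immediate early adjusted p = 0.00280) and the 3 lower ones did not, and calcium, EGFR-MAPK and cholesterol synthesis genes, described below, were higher than such lists (adjusted p = 0.00280 each). Camera called none of the last 3 lists, also not with an estimated correlation (adjusted p = 0.842, 0.977 and 0.977, respectively).

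The other signalling lists held single genes with large changes and did not pass camera. Of 13 Notch pathway genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.749), led by Dtx1 (5.65), Hey1 (2.85), Notch3 (2.10) and Mfng (1.66). Of 12 Notch ligand and secretory progenitor genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; 0.33, 0.749), with Jag2 at 1.69 and Hes6 at -0.62. Of 22 Wnt targets 9 rose and 5 fell (9 and 5 adjusted over the list alone; 0.749, higher), among them Lef1, a transcription factor of the pathway (6.23, SE 0.47), the inhibitor genes Notum (4.90) and Dkk3 (at least 13.1-fold higher), and Wif1 (1 DMSO count, ratio 88.8, 15.6 to 3543). Their mean was 1.33 and their median -0.04, or 0.08 with library size alone. Of 36 calcium, calcineurin and MEF2 genes 16 rose and 7 fell (16 and 7 adjusted over the list alone; 0.20, 0.317). Rcan2, a calcineurin regulator, had 2 DMSO counts and a ratio of 70.5 (19.2 to 587), Mef2b 2 counts and 27.5 (7.28 to 232), Mef2c 1 count and 28.4 (4.73 to 1157), and Nfatc4 3 counts and 21.7 (7.12 to 108). The calls of Mef2c and Nfatc4 were lost without DMSO replicate 1 and without Isx-9 replicate 1, respectively. Of 18 EGFR-MAPK genes 7 rose and 3 fell (7 and 3 adjusted over the list alone; 0.17, 0.749), with Tgfa at 0.77, Dusp5 at 0.74 and the receptor gene Erbb3 at -0.88. Of 14 YAP and fetal-like genes 6 rose and 0 fell (6 and 0 adjusted over the list alone; 0.57, 0.113), led by the connexin Gja1 (6.46, SE 0.59) and Anxa1 (3.02), and this list passed without DMSO replicate 1 (adjusted p = 0.0165).

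Among markers of differentiated epithelium, no list passed camera. Enterocyte markers had 3 rises and 2 falls among 21 (2 and 2 adjusted over the list alone; median -0.07, or 0.06 with library size alone; camera adjusted p = 0.863), with the peptidase gene Enpep at 1.46, a call lost with DESeq2, and Apob at 0.92. Goblet markers had 3 and 1 among 15 (0 and 0 adjusted over the list alone; 0.20, 0.863), with the chemokine gene Ccl9 at -0.70 and Fxyd3 at 0.60, each of which lost its call under 5 alternatives (Ccl9 was at -0.37 without Isx-9 replicate 1 and Fxyd3 at 0.25 without DMSO replicate 2), and Paneth markers 0 and 0 among 15 (0 and 0 adjusted over the list alone; 0.08, 0.954). Of 12 tuft markers 6 rose and 0 fell (6 and 0 adjusted over the list alone; 1.29, 0.317), including Alox5ap, a leukotriene synthesis gene (4.22), Matk (2.62) and the cyclooxygenase gene Ptgs1 (2 DMSO counts, ratio 47.1, 12.7 to 395). Of tested genes of the tuft markers' DMSO level 50.0% rose, and random lists of that level had a median of 1.10.

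Stress lists did not pass camera. Heat shock genes had 5 rises and 3 falls among 11 (5 and 3 adjusted over the list alone; median 0.13, camera adjusted p = 0.863), with the small chaperone gene Hspb1 rising by 4.07 (SE 0.29) and Hspa1b, whose reads are shared with its paralog Hspa1a, at 1.05. The p53 targets had 5 and 2 among 16 (5 and 2 adjusted over the list alone; 0.08, 0.749), with Gdf15 at 0.71 and Btg2 at 0.62. Unfolded protein and amino acid response genes had 6 and 2 among 19 (6 and 2 adjusted over the list alone), with a median of -0.03 against a mean of 0.03 and a camera direction of higher (0.954), a median of 0.10 with library size alone, and Sesn2 at -0.99. Cholesterol synthesis genes had 3 and 4 among 22 (3 and 4 adjusted over the list alone, or 5 and 3 with library size alone; median 0.01, mean -0.03, camera lower, 0.749), with Mvd at -0.71 and Hmgcs1 at 0.39. Of 7 AhR targets 2 rose and 0 fell (2 and 0 adjusted over the list alone; 0.16, 0.749), Ahrr (2.64) and Cyp1b1 (1 DMSO count, ratio 53.1, 9.16 to 2133). Of 14 interferon and antigen presentation genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; 0.38, 0.142), with H2-Ab1, an antigen presentation gene (4.16, SE 0.54), Ifit2 (2.64) and the antimicrobial genes Reg3b (3.72) and Reg3g (2.66), whose family members share sequence; the list passed without DMSO replicate 1 (adjusted p = 0.0386).

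Markers of cell types outside the epithelium also moved. Of 10 mesenchymal genes 4 were tested and these rose (4 adjusted over the list alone), too few for camera and in part fixed by the filter, since 48.0% of tested genes of their DMSO level rose: Pdgfra (3 DMSO counts, ratio 99.5, 33.7 to 485), Pdgfrb (3.31), Col1a1 (2.54) and Vim (4.42 ± 0.997 to 25.7 ± 7.56 CPM, 2.54). More of its genes were tested, under the same kind of filter, and the list passed, without DMSO replicate 1 (adjusted p = 0.0167), DMSO replicate 2 (adjusted p = 0.0386) or Isx-9 replicate 2 (adjusted p = 0.0152). Of 5 endothelial and glial genes 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 1.90, camera adjusted p = 0.425), against 56.2% of tested genes of their DMSO level that rose, Kdr (at least 15.9-fold higher), S100b (3.07) and Pecam1 (1.90), where S100b lost its call without either Isx-9 replicate and Pecam1 without Isx-9 replicate 2 or DMSO replicate 1. Of 5 immune genes Cd68 passed at -0.62, a call lost with no low-count filter and without DMSO replicate 1 (-0.38) or Isx-9 replicate 1 (-0.45), and 0 rose (0 and 1, rising and falling, adjusted over the list alone; median -0.07 and camera direction lower, 0.798, against a mean of 0.13, and a median of 0.06 with library size alone). Epcam, the epithelial adhesion gene, chosen after its values were seen, had 959 CPM in DMSO and 731 CPM with Isx-9 (log2 fold change -0.39).

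**Figure D1:**
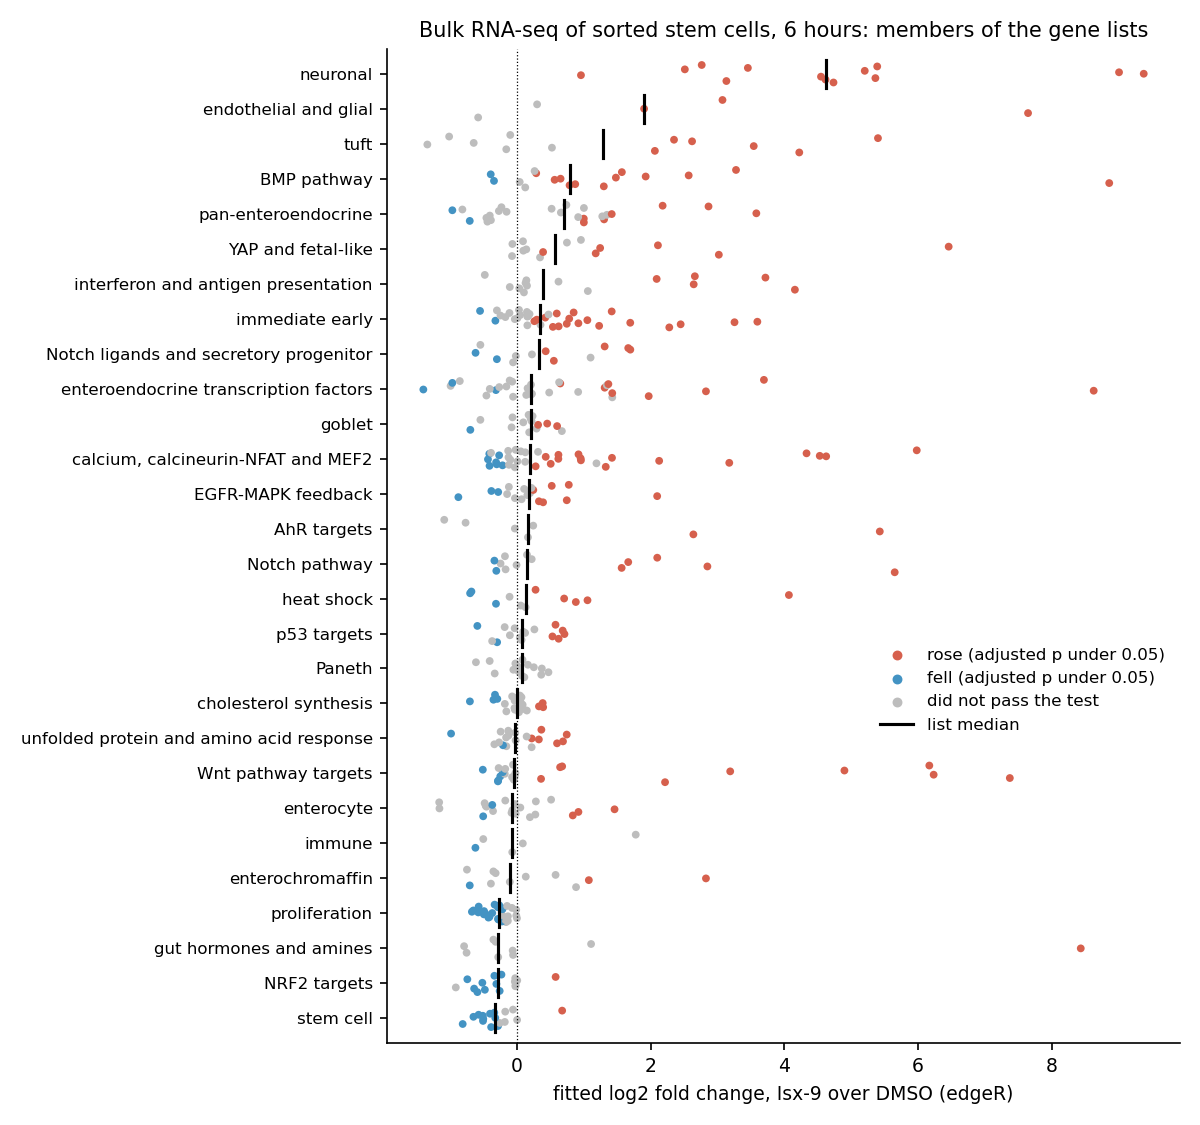
Fitted log2 fold change of every tested member of the 28 lists in sorted stem cells (x axis), 2 Isx-9 against 2 DMSO libraries, with red points for genes that rose, blue for genes that fell, grey for genes that did not pass, and a black tick at the list median. All 13 neuronal genes lie above 0 around a median of 4.62, and 18 of 28 proliferation genes are blue around a median of -0.27; for genes with 0 to 3 DMSO counts the position depends on the prior count and is no bound.

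The table of bulk differential expression that the authors deposited listed 27399 genes, of which 7051 had an adjusted p under 0.05, 4307 higher and 2744 lower. Of these, 6860 were called in the same direction by edgeR and 0 in the opposite direction. At an adjusted p of 0.01 the authors' table called 5354 genes, of which 5235 were shared.

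After 6 days, enteroendocrine-like cells were the largest class with Isx-9. They made up 4884 of 9156 cells, 53.3% (95% exact binomial interval 52.3 to 54.4%), against 7.02% (6.50 to 7.57%) with DMSO, a ratio of 7.60 (7.03 to 8.22). Stem or cycling-like cells made up 9.84% (9.24 to 10.5%) against 51.7% with DMSO, a gap that depends on naming, since an unnamed cluster with 2759 Isx-9 cells and 1 DMSO cell had the stem cell list as its nearest, with 4 markers at least 2-fold higher. Enterocyte-like, goblet-like, Paneth-like and tuft-like cells, the absorptive, mucus-secreting, antimicrobial and chemosensory types, were 9.53, 7.08, 2.35 and 3.97% of cells with DMSO and 0.131% (12 cells), 0.0655% (6 cells), 0.109% (10 cells) and 0.360% (33 cells) with Isx-9. Together these 4 classes were 22.9% (22.1 to 23.8%) of cells with DMSO and 0.666% (0.510 to 0.855%) with Isx-9. Unnamed clusters held 18.3% of cells with DMSO and 36.2% with Isx-9.

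The Isx-9 cells lay in clusters of their own. Of the EEC-like clusters, the largest, led by Chgb, Pcsk1n and Tac1, was 3710 of 3714 cells from the Isx-9 library, and one led by Kirrel2 and Neurog3 was 928 of 928. The EEC-like cells of the other 3 libraries lay in a cluster led by Ghrl, Isl1 and Neurog3, one led by Afp, Reg4 and Tph1 and one led by Gcg, Gip and Nts, to which Isx-9 gave 6, 13 and 5 cells. A further EEC-like cluster of cells with few UMIs drew 222 of its 294 cells from Isx-9. Stem or cycling-like cells of Isx-9 formed a cluster (897 of 897) led by Cym, and the unnamed Isx-9 cells lay mainly in a cluster led by Cym, Ifitm1 and Ldhb (2759 of 2761) and one led by Clu and Ly6a (513 of 513). Scrublet called 860 doublets (8.59%) in the Isx-9 library and 1, 1 and 5 in the others, so it did not work alike in the 4 libraries, and 93.1% of the 860 lay in EEC-like clusters. With called doublets kept, the Isx-9 share was 57.2% and the ratio 8.18.

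**Figure D2:**
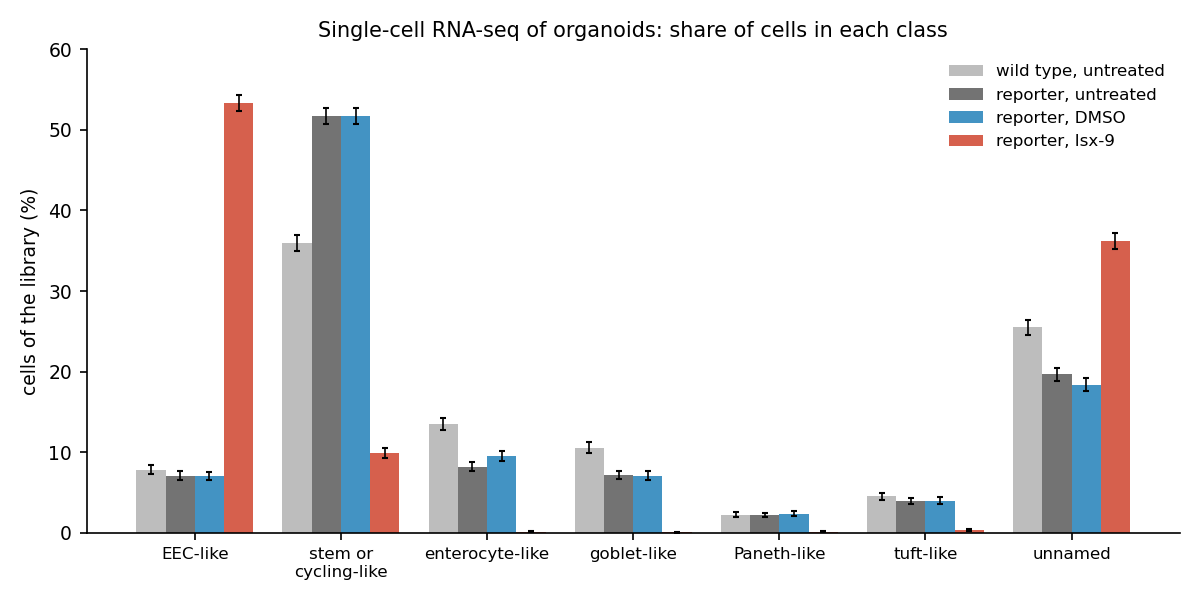
Share of cells (percent) in each of 7 classes in the 4 single-cell libraries, with exact 95% binomial intervals as error bars and 1 library per condition. EEC-like cells stand at 7.85, 7.10 and 7.02% in the wild-type, untreated reporter and DMSO libraries and at 53.3% with Isx-9, and stem or cycling-like cells at 51.7% with DMSO and 9.84% with Isx-9, where the unnamed class includes 2759 cells whose nearest list was stem cell.

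Over all cells, the granin, enteroendocrine and neuronal genes were higher with Isx-9 and genes of the absorptive, goblet and Paneth lineages lower. Chgb, a granin, was at 7387 CPM against 479 with DMSO (ratio 15.4, 15.3 to 15.5), Neurog3 at 425 against 22.6 (18.8, 18.1 to 19.5), Neurod1 at 143 against 14.6 (9.79, 9.32 to 10.3) and Chga at 1019 against 156 (6.55, 6.45 to 6.65). Lgr5 was at 216 against 152 (1.42, 1.39 to 1.45), whereas Olfm4 was at 160 against 2158 (0.0739, 0.0727 to 0.0751) and Mki67 at 72.6 against 164 (0.444). Lyz1 (0.367), Muc2 (0.0623), Alpi (0.178) and Dclk1 (0.333), markers of Paneth, goblet, enterocyte and tuft cells, were lower. The highest ratio was that of Cym, chymosin, a milk-clotting protease, at 518 CPM against 0.0945 (ratio 5475, 3134 to 10596), followed by Wfdc2 (1094), Hspb1 (879), Itm2a (540), Sbspon (404), Fn1 (379), Rdx (334), Uchl1 (318), Lbp (315) and Slc2a3 (303). The lowest were Fabp1, a fatty acid binding protein of enterocytes, at 0.376 CPM against 604 (0.000623), Dmbt1 (0.00177), Gsta1 (0.00217), AY761184 (0.00388), Defa34 (0.0104), Defa29 (0.0105), Guca2b (0.0125), Cfhr2 (0.0157), Smlr1 (0.0165) and Reg3a (0.0168). Members of the Defa and Reg3 families share sequence, so their single values are uncertain.

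The median log2 ratio over all measured genes was 0.33, or -0.00172 with TMM-scaled sums, so list medians were placed among random lists of similar expression. Pan-enteroendocrine genes had a median of 3.21 (above all random lists; 24 of 25 at least 2-fold higher, 0 lower), with Pcsk1n at a ratio of 51.6, Snap25 at 19.7 and Cplx2 at 15.8. Neuronal genes had a median of 3.97 (20 of 21 higher), with Stmn3 at 203 and Elavl3 at 138 and with Stmn2, which had 0 UMIs in DMSO, at least 2715-fold higher. Enteroendocrine transcription factors (median 1.88, 23 higher and 1 lower of 30), hormones and amines (1.26, 10 and 4 of 18), enterochromaffin genes (1.40, 10 and 2 of 13), YAP and fetal-like genes (2.12, 12 and 2 of 16) and Wnt targets (1.06, 12 and 1 of 22) lay above all random lists, except that the enterochromaffin list lay above 99.99% of them. Mesenchymal genes (2.03, 6 and 0 of 8), among them Vim at a ratio of 10.2, lay above all of them too. Lef1 (ratio 282), Wif1 (122), Pax4 (21.4), Runx1t1 (15.4) and Clu, a marker of regenerating and fetal-like epithelium (8.19 to 417 CPM, 50.9), were examples. Medians of goblet (-2.33, 9 of 15 lower), Paneth (-1.79, 14 of 16), enterocyte (-1.67, 14 of 22), tuft (-1.45, 10 of 16) and proliferation genes (-0.92, 12 of 28) lay below all random lists, with Ccl9 at 0.0176, Defa17 at 0.0191, Apoa1 at 0.0231, Lrmp at 0.0789 and Ccna2 at 0.344. The stem cell list lay at 0.33 (95.8th percentile; 6 higher and 2 lower of 18), about the median of all genes, and at -0.05 with TMM-scaled sums.

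Within EEC-like cells, Chgb and Neurog3 were higher and most of the named hormone genes lower with Isx-9. The EEC-like cells of DMSO and Isx-9 lay in largely separate clusters, and 928 Isx-9 cells lay in one led by Kirrel2 and Neurog3. The compared cells thus differ in their make-up, and the ratios do not separate this from changes within a cell type. Chgb was at 19213 CPM against 9568 with DMSO (ratio 2.01, 1.99 to 2.02), Neurog3 at 1089 against 422 (2.58, 2.48 to 2.68) and Tac1, the substance P precursor, at 3384 against 2540 (1.33, 1.31 to 1.35). Gcg, the glucagon and GLP-1 precursor, was at 35.8 against 4337 CPM (0.00826, 0.00781 to 0.00874), Ghrl, ghrelin, at 48.0 against 4995 (0.00962), Nts, neurotensin, at 30.3 against 1797 (0.0168), Gip at 347 against 10793 (0.0322), Pyy at 53.3 against 796 (0.0669) and Sst, somatostatin, at 212 against 1700 (0.125). Tph1, which makes serotonin, was at 192 against 606 (0.317), Cck at 4415 against 8152 (0.542), Sct at 1054 against 1285 (0.820) and Chga at 2638 against 3112 (0.848). EEC-like cells of libraries without Isx-9 differed too. Tac1 was at 2759 CPM in the untreated reporter and 1453 in the wild type (1.90), and Cck and Sct were at 14550 and 1848 CPM in the untreated reporter. The ratios of Tac1, Cck and Sct were therefore not set apart from differences between libraries. Chga differed less, at 2924 CPM in the untreated reporter and 2883 in the wild type. The highest ratios were those of Basp1 (176, 98.5 to 353), Igfbpl1 (67.5), Lpl (34.3), Tesc (33.4), Epha5 (31.7), Kirrel2 (31.1), Rtn1 (28.9), Celf4 (28.8), Meg3 (28.7) and Nsg2 (28.1). The lowest, besides Gcg, Ghrl, Nts, Gip and Olfm4 (0.0321), were Afp (0.00267, 0.00213 to 0.00331), Guca2a (0.0109), Clca4b (0.0210), Otc (0.0246) and Trpa1 (0.0302), an irritant receptor of enterochromaffin cells. The median log2 ratio of all genes in these cells was 0.22. As a list, hormones had a median log2 ratio of -1.02 and proliferation genes of -2.41, both below all random lists, and neuronal genes of 2.97, above all of them.

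Shares of hormone-positive cells among EEC-like cells, thinned to 2000 UMIs, moved the same way for these peptides. Gcg was seen in 12.4% of DMSO and 0.848% of Isx-9 EEC-like cells, Ghrl in 21.9 and 1.38%, Gip in 14.4 and 1.70%, Nts in 2.51 and 0.681%, Pyy in 8.19 and 4.36% and Sst in 2.17 and 0.873%. The same 6 of 9 peptides were lower when cells were not thinned and with at least 3 UMIs. The median depths of these DMSO and Isx-9 cells before thinning were 8154 and 7245 UMIs. In enterocyte-like cells of the DMSO library (median 11463.5 UMIs), as a background from free RNA, the shares were 2.40% for Gcg, 3.20% for Ghrl, 3.86% for Gip, 0.40% for Nts, 0.133% for Pyy and 0.266% for Sst. The Isx-9 library had only 12 enterocyte-like cells, so its background was read in all cells that were not EEC-like (median 13306.5 UMIs). There Gip was seen in 1.36%, close to its share in EEC-like cells. Tac1 was seen in 38.3 and 69.7% of EEC-like cells, Neurog3 in 28.3 and 41.4%, Tph1 in 30.3 and 18.8% and Chgb in 67.4 and 89.4%. No background is given here for Tac1, Neurog3 and Tph1, so a part from free RNA was not excluded. In cells that were not EEC-like, Chgb was seen in 2.19% with DMSO and 23.9% with Isx-9. The shares of Chga, Cck and Sct ran against their CPM, and no order was read from them.

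**Figure D3:**
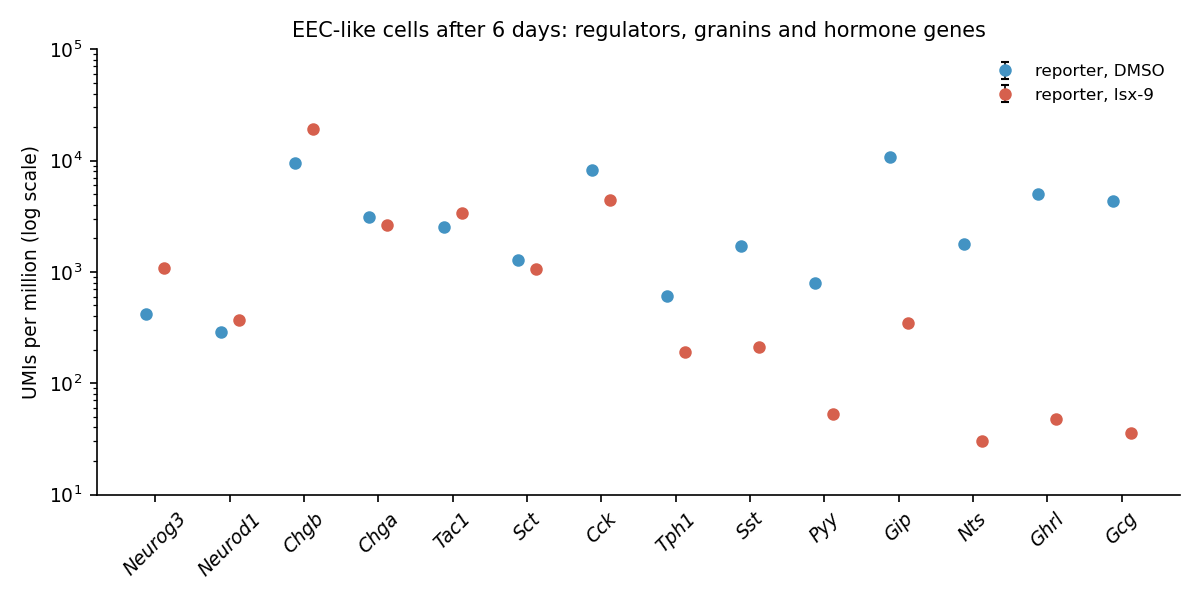
CPM of 14 genes in EEC-like cells (log axis) with DMSO and with Isx-9, 1 library each, with exact 95% Poisson intervals, mostly smaller than the points, that cover counting error only. Gcg lies at 4337 and 35.8 CPM and Ghrl at 4995 and 48.0 CPM with DMSO and Isx-9, whereas Chgb lies at 9568 and 19213 CPM.

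The untreated reporter and wild-type libraries compare the lines before treatment, with 1 library each, so line and library cannot be separated. Chgb, the locus that carries the reporter, was at 529 CPM in the reporter and 725 CPM in the wild type (ratio 0.730, 0.723 to 0.737), and in EEC-like cells at 10782 and 13451 CPM (0.802). Gcg was at 376 against 746 CPM (0.505), Pyy at 89.6 against 222 (0.404) and Gip at 353 against 195 (1.81), while Chga (0.928) and Neurog3 (1.09) lay closer to 1. EEC-like cells made up 7.10% (6.59 to 7.63%) and 7.85% (7.29 to 8.43%) of cells, and stem or cycling-like cells 51.7 and 35.9%. The last pair may depend on naming, since an unnamed cluster led by Xist held 284 reporter and 1482 wild-type cells. Its nearest list was stem cell, but 0 markers of that list were at least 2-fold higher, so the class of these cells was not settled. The pan-enteroendocrine list had a median log2 ratio of -0.05 (15.4th percentile), the goblet list of -0.31 and the YAP and fetal-like list of -0.75 (both below all random lists). In the wild-type library 39.2% of cells had UMIs of Xist and none of 4 Y-linked genes and 39.9% the reverse, whereas in the 3 reporter libraries 0.0446 to 0.109% had Xist alone. Against the Y-linked wild-type cells only, chosen after seeing the data, the Chgb ratio was 0.743. The wild-type side was picked by a detected UMI and the reporter side was not, so the 2 sides are not like for like. Chgb was at 712 CPM in the Y-linked wild-type cells and at 580 CPM in the wild-type cells with Xist alone, closer to the 529 CPM of all reporter cells.

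The DMSO and untreated reporter libraries differed little. The correlation across genes of their log2 CPM was 0.999, against 0.992 for reporter and wild type and 0.877 for Isx-9 and DMSO (genes are not independent replicates). Chgb (0.906), Neurog3 (0.978) and Chga (1.07) had ratios of DMSO to untreated near 1, and the pan-enteroendocrine list a median of -0.01 (46.5th percentile). Single hormones differed more, with Pyy at 40.3 against 89.6 CPM (0.450), Gcg at 0.577, Cck at 0.573 and Gip at 1.52, and for Pyy, Gcg and Gip these ratios, within 1 line, were of similar size to those between reporter and wild type.

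Genes called in sorted stem cells at 6 hours mostly lay on the same side in the single-cell data at 6 days, although the lines, cells and times differ. In stem or cycling-like cells, 3474 of 3719 genes that rose in bulk were higher with Isx-9 (93.4%, against 63.3% of all measured genes), and 2185 of 3188 that fell were lower (68.5%, against 36.7%). Relative to the median log2 ratio of all genes there (0.16), the shares were 89.6 and 84.9%. For changes of at least 2-fold in bulk, 2310 of 2378 were higher (97.1%) and 63 of 77 lower (81.8%). Genes needed at least 20 UMIs over both sums, so those near 0 in DMSO cells were measured only through their Isx-9 UMIs, which favours the higher side. Between all DMSO and all untreated reporter cells, neither treated with Isx-9, 50.5% of the genes that rose in bulk were higher (against 44.7% of all measured genes) and 61.3% of those that fell were lower (against 55.3%).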

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

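Of the tests in this part, the one of free RNA in the wild-type library and the comparison limited to Y-linked wild-type cells were chosen after the result was seen.

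Chga and Lgr5 had changes of opposite sign at the 2 time points. For Chga the log2 ratio of Isx-9 to DMSO was 2.70 over all single cells at 6 days and the log2 fold change -0.71 in sorted stem cells at 6 hours (-0.31 without DMSO replicate 2, adjusted p = 0.323). For Lgr5 these values were 0.50 and -0.18, and the bulk value did not pass its test. The median log2 ratio of all measured genes over all single cells was 0.33, so the Lgr5 value of 0.50 holds this shift. The differences between the times were not tested, and the lines, the cells and the times all differ.

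In the wild-type library, which no treatment comparison uses, 39.2% of cells (38.2 to 40.3%) had UMIs of Xist, the RNA of the inactive X chromosome, and none of 4 Y-linked genes, and 39.9% had Y-linked UMIs and no Xist, a split not seen in the reporter libraries. Barcode swapping from the reporter libraries was argued against, since Y-linked wild-type cells shared a barcode with a reporter library 1.082 times as often as Xist cells (0.946 and 0.874%), under the bound of 2 written before. Free RNA in the droplets would put both kinds of UMI into most cells, which the split itself goes against. Of the cells with either kind 7.695% had both, a value that the split already kept low and that adds no independent evidence. Hoxb9, a posterior homeobox gene, was at 80.1 CPM in the Xist cells, 23.4 CPM in the Y-linked cells and 2.56 CPM in the untreated reporter, and EEC-like cells made up 7.31, 7.48 and 7.10%. These wild-type cells were picked by a detected UMI and the reporter cells were not, so the shares are not like for like. A wild-type culture from animals of both sexes may account for the split; the labels name none, and no biological explanation was tested.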

How the results depend on the processing

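Scaling by library size alone, random lists of the same level, marker lists left out of the clustering and the Y-linked wild-type cells were alternatives chosen after seeing the data. The bulk count stayed within 1.5 times its value of 8243 and kept its majority of higher genes with DESeq2 (7123), RLE factors (8224), no low-count filter (6733), a CPM filter (7857), library size alone (7570) and limma-voom (8241). The replicate numbers did not pair the libraries (correlation across genes 0.0110), and the replicate block gave 8131. Leaving out 1 library gave 5661 to 7626 calls, 3599 to 4536 higher and 2062 to 3090 lower, with the lone library assumed to vary like the others. Lower genes numbered 2095 with library size alone, where the median of all genes shifted. A minimum of 2-fold left 3510 genes, 154 of them lower, by its own construction. Of 130 named bulk genes, 26 lost their call under at least 1 alternative (90 values), 2 gained one (Chgb and Lgr5, 4 values), and 1330 values kept direction and side. Of the list calls (3 higher, 3 lower), an estimated correlation left 0 and 0. By fry, which asks whether a list's genes move 1 way and not whether they differ from other genes, 2 lists were higher (BMP, and calcium, which camera did not call, adjusted p = 0.0384) and 0 lower. Random lists of the same DMSO level, or of the same mean level over the 4 libraries, gave 6 higher and 0 lower. Leaving out 1 library gave 3 to 6 higher and 2 to 3 lower. The cause was not tested.

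The EEC-like ratio of 7.60 stayed between 6.65 and 9.24: 6.68 at Leiden resolution 2, 6.65 with the stricter cell filter, 9.24 with no filter on cells and 8.70 for the definition by UMIs alone, and within its interval at resolution 0.5 (7.58), without the enteroendocrine lists (7.68) or any marker list (7.56) and with each library clustered alone (7.06). The 4 differentiated classes were 30.6% of DMSO cells at resolution 0.5, 18.7% at 2, 21.5% without the enteroendocrine lists, 26.6% with the stricter filter and 24.6% with each library alone, and 0.907 and 0.491% of Isx-9 cells at resolutions 0.5 and 2. With cells weighted alike, the pan-enteroendocrine, proliferation and stem cell medians were 2.94, -1.19 and 0.25, with no filter proliferation was -0.89, and with TMM-scaled sums they were 2.84, -1.31 and -0.0487, the stem cell list reversed because that scaling removes the shift of all genes. Bulk genes that fell were lower in 61.6% of cases over all cells, against 28.5% of all measured genes there. Between all untreated reporter cells and Y-linked wild-type cells the Chgb ratio was 0.743. Single class shares moved beyond their intervals in 102 of the values and not in 58, and single-cell gene levels in 48 and 15. Depth limits classes with few Isx-9 cells, such as 6 goblet-like cells. The causes were not tested.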

Other observations

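Of the tests in this part, the one of a technical difference of the Isx-9 library and a set-aside test of neuronal genes outside EEC-like cells were chosen after the result was seen.

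Further gene lists were compared at 6 days, and some lay outside most random lists. Over all cells, NRF2 targets had a median log2 ratio of -0.50 (0.01st percentile of random lists; 7 of 16 at least 2-fold lower), with Gsta1 at a ratio of 0.00217 and Nqo1 at 0.188. Unfolded protein genes had -0.23 (0.26th percentile, Chac1 at 0.167) and cholesterol synthesis genes -0.21 (2.36th percentile, Idi1 at 0.604). Interferon and antigen presentation genes had 0.78 (99.6th percentile; 8 of 20 at least 2-fold higher), with H2-Ab1 at 30.1 and Cd74, the invariant chain, at 44.5, and p53 targets 0.63 (98.9th percentile, Zmat3 at 3.48). The lists that follow lay among the random lists. BMP genes had 0.64 (92.1st percentile, Bambi at 8.81), Notch ligand and secretory progenitor genes 0.65 (86.9th percentile, Dll3 at 6.27 and Atoh1 at 0.0749), calcium genes 0.37 (87.1st percentile, Rcan2 at 42.0) and endothelial and glial genes 1.10 (82.7th percentile, Pecam1 at 32.0). Notch pathway (0.41, 46.0th percentile), heat shock (0.19, 64.1st), immediate early (0.19, 26.8th), EGFR-MAPK (0.20, 29.2nd), AhR (0.21, 24.8th) and immune genes (0.29, 22.1st) did so too, although Dtx1 (415) and Laptm5 (35.2) stood out.

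Within stem or cycling-like cells, the medians of pan-enteroendocrine (1.61), neuronal (2.76) and YAP and fetal-like genes (2.63) were above all random lists with Isx-9. Of the 901 Isx-9 cells of this class, 897 lay in 1 cluster named by proliferation markers. Of 4636 DMSO cells, 1823 lay in a cluster led by Olfm4 and Gkn3, which also had Mcm genes of the proliferation list among its leading genes. The other DMSO cells lay in clusters named by proliferation markers. The compared cells thus differ in their make-up, and no change of proliferation genes was read from them. Chgb was seen in 22.1% of these Isx-9 cells (median 17856 UMIs) and 1.95% of those with DMSO (15487 UMIs), after thinning, and free RNA from the many EEC-like cells was not excluded as a source. Within EEC-like cells immediate early genes had a median of -0.98, below all random lists. Outside the EEC-like cells the median log2 ratio of neuronal genes was 2.501, and the test was set aside because free RNA from EEC-like cells was not excluded.

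At 6 hours, 362 genes with 0 counts in both DMSO libraries reached 1 CPM in Isx-9 stem cells, and olfactory receptor genes, listed for 62 genes with shared sequence, took 1919 counts against 179. RNA from cells that are not epithelial stays open: 99.58% of these genes' UMIs in the Isx-9 single-cell library lay in cells with Epcam, but so did 99.7% of all UMIs, and 98.4% of cells had Epcam, so the bound of 90% set before the test was wrong and the measure decides nothing. In the bulk libraries the 4 mesenchymal genes tested, of 10, and 3 of 5 endothelial and glial genes rose, as did 48.0 and 56.2% of tested genes of their DMSO levels. Camera did not test the first list and did not call the second, and 0 of 5 immune genes rose. The cells were sorted as stem cells by Lgr5-EGFP, and how far the sort left out cells that are not epithelial was not measured. Genomic DNA or unspliced background reads were not told apart from transcription for each of the 362 genes. Of 308 measured genes 130 (42.21%) were at least 4-fold higher in the Isx-9 single-cell library, short of the 50% set before the test. This was so for 129 of 860 measured other genes at 0 in DMSO and 9.29% of all genes. Summed over the genes, Isx-9 cells held 1694 CPM (stem or cycling-like), 1625 CPM (unnamed) and 3119 CPM (EEC-like), against 27.99 CPM in all DMSO cells. Some of the genes thus had more UMIs in a separate Isx-9 library at 6 days. A sum can rest on few genes, and there was 1 library per treatment, so background reads stay open for the others. A response to Isx-9 stays open as the design's own explanation, with 2 libraries per group.

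Isx-9 cells formed clusters of their own, with 1 library per treatment. Lower depth was argued against by the cells with at least 2000 UMIs, each thinned to that number. Among these a mean of 98.3% of the neighbours of Isx-9 cells were Isx-9 cells, against 38.2 to 46.7% of own cells in the other libraries. A technical difference of that library as the whole cause was set against the bulk data. Of the genes that rose at least 2-fold in separate libraries at 6 hours, 97.14% were higher in stem or cycling-like Isx-9 cells. This was so for 63.3% of all genes, and the excess passed the bound set for the test. The test cannot decide the question. Genes near 0 in DMSO cells were measured only through their Isx-9 UMIs, and the 63.3% is not matched on level. A technical difference stays open. A response to the treatment could give both the 98.3 and the 97.14%, as a hypothesis found and tested on the same data. Effects of a single culture stay open.

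A hypothesis was that neuronal genes rose at 6 hours because stem cells had fewer transcripts of Rest, a repressor of neuronal genes. The prediction was a fall of Rest, which was chosen by the hypothesis and not by the rule for named genes. Its log2 fold change was -0.008468 (SE 0.11, adjusted p = 0.961, edgeR quasi-likelihood, Benjamini-Hochberg, n = 2 each), with 66.6 ± 2.41 CPM in DMSO and 66.2 ± 10.8 CPM with Isx-9. The values argue against lower Rest transcript levels; the activity of the protein was not measured.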
